A study of Homo sapiens with 4 samples.

How the data were processed

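Data from 4 arrays of the human colon cancer cell line HCT116 were analysed: 2 arrays of cells transfected with a control siRNA and 2 of cells transfected with siRNA against TRA2B, an RNA-binding splicing regulator. Per the labels' protocols, RNA was taken 48 h after transfection with a lipid reagent, and total RNA was end-labelled with the dye Cy3 by ligation of a labelled cytidine bisphosphate and hybridised to Agilent human miRNA arrays, 1 sample per array. The titles number the arrays of each group 1 and 2. The labels say neither whether these numbers are repeat transfections or different siRNAs nor whether they come from separate cultures. The p-values of single miRNAs and of the array-wide signal therefore measure only the spread between these arrays, which may be technical. Some tests below set a list of miRNAs against the others and measure spread between miRNAs on the same arrays.

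The deposited files are scanner output of Agilent Feature Extraction 9.5.3.1, per the file headers. The values used are the processed signal of each spot, an intensity on a linear scale from which the authors' software had subtracted the background, per the file headers, with no scaling between arrays. The deposited series table held the same intensity values: over 15739 spots per array, 100% were equal to the processed signal within a relative tolerance of 1e-06. Its medians were 1.10, 1.44, -1.11 and -2.61 for control siRNA 1, TRA2B siRNA 1, control siRNA 2 and TRA2B siRNA 2, so it is linear, not centred and not scaled. The arrays carry 851 human and 88 viral miRNAs, with 16 spots per miRNA, and name them by an older miRBase release, in which a star marks the less abundant strand of a precursor. No array had a saturated spot. No probe on the array measures TRA2B mRNA, so the knockdown itself was not checked here.

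Per the file headers, both arrays numbered 1 lay on one slide with one scan time and both arrays numbered 2 on another. These are called slide 1 and slide 2. Each slide holds 1 array of each group, so the number, the slide and the scan are the same block. Across the tested miRNAs, the difference between slides in the control group and that in the TRA2B group had a correlation of 0.92, over miRNAs that are not independent replicates. The labels do not say that the numbers pair the samples, and the block therefore stands beside the unblocked test, together with the values within each slide. A slide holds 1 array per group, so within a slide there is no test.

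Spots flagged as outliers (6.76% to 7.85% of human spots per array) were left out and the others of a probe averaged. Each array was divided by its 75th percentile over the 260 probes of the 125 human miRNAs detected on all 4 arrays. Values under a floor, the highest over the arrays of the 5th percentile of the scaled signal of detected probes, were set to it, log2 was taken and the probes of a miRNA were averaged. Detection is the software's own call per miRNA. A miRNA was tested if it was detected on both arrays of at least 1 group, which gave 135 miRNAs. All 135 had more than 1 probe, and for 2 of them probes went opposite ways by over 0.2 on the log2 scale. Because scaling removes any change that most miRNAs share, changes before scaling, on the same floor rule, are given as well.

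The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all tested miRNAs, threshold 0.05), with no block in the design fixed before the data were examined and with the slide as a block beside it. The unblocked fit has 2 residual degrees of freedom per miRNA and the blocked fit 1. In the blocked fit of scaled values the estimated prior gave every miRNA the same pooled spread, so its calls rest on the assumption that all miRNAs vary alike. The overall signal, the median unscaled log2 signal over the probes detected on all arrays, was compared by a two-sided exact permutation test, which with 2 against 2 arrays cannot go below 0.33. A set of 24 miRNA lists (270 entries, 238 matched to the array) was written before the data were examined. It covers families and clusters, biogenesis classes, colon and cancer miRNAs and markers of other cell types. The 16 lists with at least 3 tested members were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation and fry beside it. For passenger strands, listed arm names were matched to the star names of the array, a step beyond the matching rule set in advance.

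Named miRNAs follow a rule set in advance: miRNAs past the threshold whose groups do not overlap, or, with fewer than 10 of those, up to 10 in each direction at an unadjusted p under 0.05 whose groups do not overlap, up to 4 members of each tested list with the largest absolute change, and 10 miRNAs fixed by name. The miRNAs that passed in the blocked fit were added to the named ones after the data were seen, as were those outside these rules that are pointed out as such. Tested on simulated data with the spread of these arrays (135 miRNAs, 50 simulations), the unblocked fit of this comparison called 3.8% of miRNAs changed by 0.5 on the log2 scale, 31.6% of those changed by 1 and 91.2% of those changed by 2, and the blocked fit 64.4%, 98.2% and 100%. With the fragments list described below shifted by 0.5, camera at the preset correlation called it in 74% of unblocked simulations, fry in 6% and camera with an estimated correlation in 0%. The simulated noise was independent between miRNAs, and in the blocked simulations all miRNAs had the same spread. These rates therefore hold only where those assumptions do. Detection was 181, 164, 133 and 130 of the 851 human miRNAs in the array order above, and the median coefficient of variation between spots of a detected probe was 6.84% and 7.37% on slide 1 and 11.7% and 11.4% on slide 2. The number of arrays limits the precision.

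Alternatives were other scalings (none, quantile, bright control probes, the 75th percentile over all human probes), Agilent's total gene signal, the deposited series values, other filters and floors, an intensity trend with robust spread, a plain 2-fold rule, the slide block and leaving out each array. Added after seeing the data were normexp background correction on the median signals, since these files hold no mean signal, the block combined with other settings, and the median signals for the overall level.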

Results

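The experiment asked how lowering TRA2B, an RNA-binding protein that regulates splicing, affects the miRNAs of colon cancer cells. HCT116 cells, an epithelial colon cancer line, were transfected with control siRNA or TRA2B siRNA, and miRNAs were measured 48 h later on 4 one-colour miRNA arrays, 2 per group. Control siRNA 1 and TRA2B siRNA 1 lay on slide 1, and control siRNA 2 and TRA2B siRNA 2 on slide 2. Of 851 human miRNAs, 181 were detected with control siRNA 1, 164 with TRA2B siRNA 1, 133 with control siRNA 2 and 130 with TRA2B siRNA 2. No miRNA was detected on both arrays of one group and on neither of the other. Slide 2 was dimmer, with scaling factors of 154 and 115 intensity units against 298 and 203 on slide 1.

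The first question was whether the miRNA pool as a whole differed. Before scaling, most miRNAs were dimmer with TRA2B siRNA than with control siRNA on the same slide: 118 of the 135 tested miRNAs were lower on both slides, 9 were higher on both and 8 went opposite ways. The median tested miRNA stood at 0.654 of its control signal on slide 1 and at 0.712 on slide 2. Among the lower ones were miR-21, an oncogenic miRNA abundant in many tumours, at -0.63 and -0.37 on the log2 scale on slides 1 and 2, the growth-restraining let-7a at -0.74 and -0.48, miR-17 of the MYC-driven cluster that runs from miR-17 to miR-92a at -0.68 and -0.77, and the epithelial miR-200c at -0.66 and -0.78. With the slide as a block, limma called 112 miRNAs lower and 2 higher before scaling. A difference in brightness between arrays moves all miRNAs together, so these calls are not separate pieces of evidence. The 2 higher ones were miR-1246, at 0.28 and 0.62, and miR-1915, at 0.44 and 0.36. For miR-1246 the direction on slide 1 turned with the summary, as its total gene signal was 298 with control siRNA 1 and 288 with TRA2B siRNA 1.

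The array-wide level was lower with TRA2B siRNA on both slides, and the slides differed by more than the groups. The median log2 signal of probes detected on all arrays was 6.19 ± 0.73 (SD, n = 2) with control siRNA and 5.56 ± 0.68 (SD, n = 2) with TRA2B siRNA, a difference of -0.63 (exact permutation test, two-sided, p = 0.667, where 0.33 is the smallest possible). That test counts the difference between slides as spread. The difference was -0.66 within slide 1 and -0.60 within slide 2, so with the slide as a block it was -0.63 ± 0.05 (SD of the 2 within-slide differences). It was larger than that spread. An exact two-sided test with groups exchanged within slides, added after the data were seen, gave p = 0.5, the smallest that 2 slides allow. It was -0.12 without control siRNA 1, -0.15 without TRA2B siRNA 2, -1.11 without TRA2B siRNA 1 and -1.14 without control siRNA 2, each of which compares arrays across the slides. The 5 bright control probes, whose targets the files do not name, differed by a median of -0.43 on slide 1 (-0.51 to -0.37) and by -0.10 to 0.10 on slide 2, with 3 of 5 below 0. Relative to the median control probe of each array, the miRNA level was -0.21 on slide 1 and -0.62 on slide 2. From median spot signals less local background, a setting added after the data were seen, it was -0.39 (-0.48 and -0.30 on slides 1 and 2). The 6 labelling control probes of the dmr type were at background on every array.

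**Figure D1:**
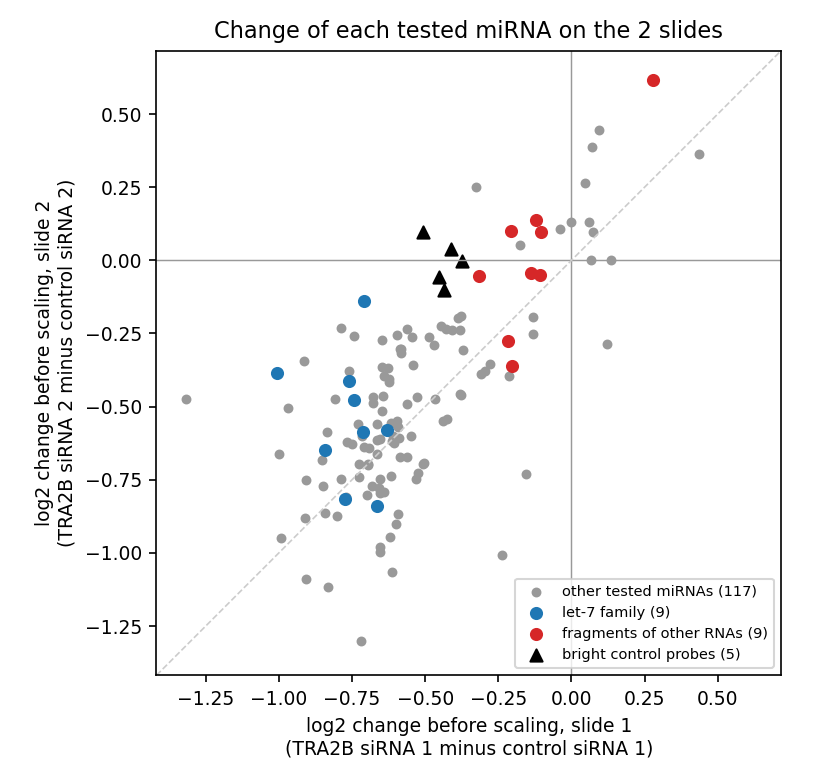
Each point is 1 of the 135 tested miRNAs or 1 of the 5 bright control probes, with the log2 change before scaling (TRA2B siRNA minus control siRNA) on slide 1 on the x axis and on slide 2 on the y axis, and a dashed line where both are equal. Most miRNAs, the let-7 family included, lie below 0 on both axes, while the 9 fragments of other RNAs lie around 0 (medians -0.14 and -0.04) and the control probes lie from -0.51 to -0.37 on slide 1 and from -0.10 to 0.10 on slide 2.

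The second question was which miRNAs changed relative to the rest once each array was scaled. Scaling moved the median change of the tested miRNAs from -0.58 to -0.12. The miRNA with the clearest separation was miR-923, now regarded as a piece of 28S ribosomal RNA, at 0.76 ± 0.26 (SE) on the log2 scale, with 0.65 on slide 1 and 0.87 on slide 2. It had an unadjusted limma p of 0.034 and did not pass the adjustment. No miRNA passed: limma called 0 of 135 (smallest adjusted p = 0.988), 1 had an unadjusted p under 0.05, the plain 2-fold rule called 0, and groups of 29 miRNAs did not overlap (21.5%, where chance gives 33.3%). Scaled levels differed more between slides than between groups: the median absolute difference was 0.37 between the control arrays, against 0.15 and 0.26 between the groups within slides 1 and 2.

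With the slide as a block, limma called 29 miRNAs, 19 higher and 10 lower relative to the array's scaling. The largest rises were those of miR-1246, a fragment of the U2 spliceosomal RNA (0.91 ± 0.15, SE), miR-1915 (0.89 ± 0.15), miR-923 (0.76 ± 0.15), miR-574-3p (0.72 ± 0.15) and miR-494 (0.64 ± 0.15), each higher on both slides. The largest falls were those of miR-425 (-0.71 ± 0.15), miR-185 (-0.55 ± 0.15), miR-18a of the miR-17 to miR-92a cluster (-0.52 ± 0.15), miR-324-5p (-0.49 ± 0.15) and miR-15b (-0.48 ± 0.15), each lower on both slides. The SE is the same for all because the fit pooled 1 spread over the 135 miRNAs. The slide 2 values of miR-425 and miR-185, and of miR-98 and miR-203, also called lower, include probe signal set to the floor. The size of these falls therefore depends in part on the floor. With the floor at the 20th percentile, the blocked fit called 16 higher and 6 lower. The split of higher against lower calls moved with the scaling: 18 and 8 with quantile normalization, 0 and 3 with bright control probes, and 2 and 112 with no scaling, each with the block. From Agilent's total gene signal with the block it was 19 and 2, so most of the falls were not called from that summary. Of the 29, 12 were also called before scaling.

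Among the lists fixed in advance, 1 of 16 passed: array entries now known as fragments of tRNA, snRNA, vault RNA or other longer RNAs, which are not typical products of the miRNA-processing enzymes DROSHA and DICER. All 9 tested members were higher on both slides after scaling, where 28 of all 135 tested miRNAs were. Their median log2 change was 0.41 (0.42 on slide 1 and 0.38 on slide 2), against -0.12 for all tested miRNAs. The leading members were miR-1246 (0.83 and 0.99 on slides 1 and 2), the tRNA-derived miR-1274a (0.43 and 0.56) and miR-1260 (0.45 and 0.52), and miR-720 (0.35 and 0.52). The list passed with camera at the preset correlation (adjusted p = 4.7e-05, and 1.1e-05 with the slide block). That test weighs the members against the spread between miRNAs on the same arrays, not against the spread between arrays. It did not pass with an estimated correlation (adjusted p = 0.59, and 0.83 with the slide block), and fry gave an adjusted p of 0.66, or 0.074 with the slide block. The correlation was estimated at -0.006 (-0.11 with the slide block), below the preset 0.01, though from few arrays. The lost call therefore does not show that the members vary together. With an estimated correlation, camera uses the residual degrees of freedom of the fit, 2, or 1 with the slide block. At the preset correlation its degrees of freedom follow from the number of miRNAs, so the 2 settings do not count the same replicates. Of the list's members, 0 passed without the block, also when adjusted over the list alone. With the block 6 rose, again 6 when adjusted over the list alone. Among all 135 tested miRNAs, 19 rose with the block, so most of these rises lay outside the list. Before scaling the same list lay near 0, with a median of -0.14 on slide 1 and -0.04 on slide 2. Of its 9 members, 5 were then lower on both slides and 1 was higher on both. The blocked fit before scaling called 1 member higher (miR-1246) and 1 lower (miR-1275, -0.20 and -0.36 on slides 1 and 2). The rise of the list is thus relative to the other miRNAs, which it exceeded by 0.54 after scaling and 0.52 before it. The excess was 0.27 with no filter on dim miRNAs and 0.23 with normexp background correction.

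**Figure D2:**
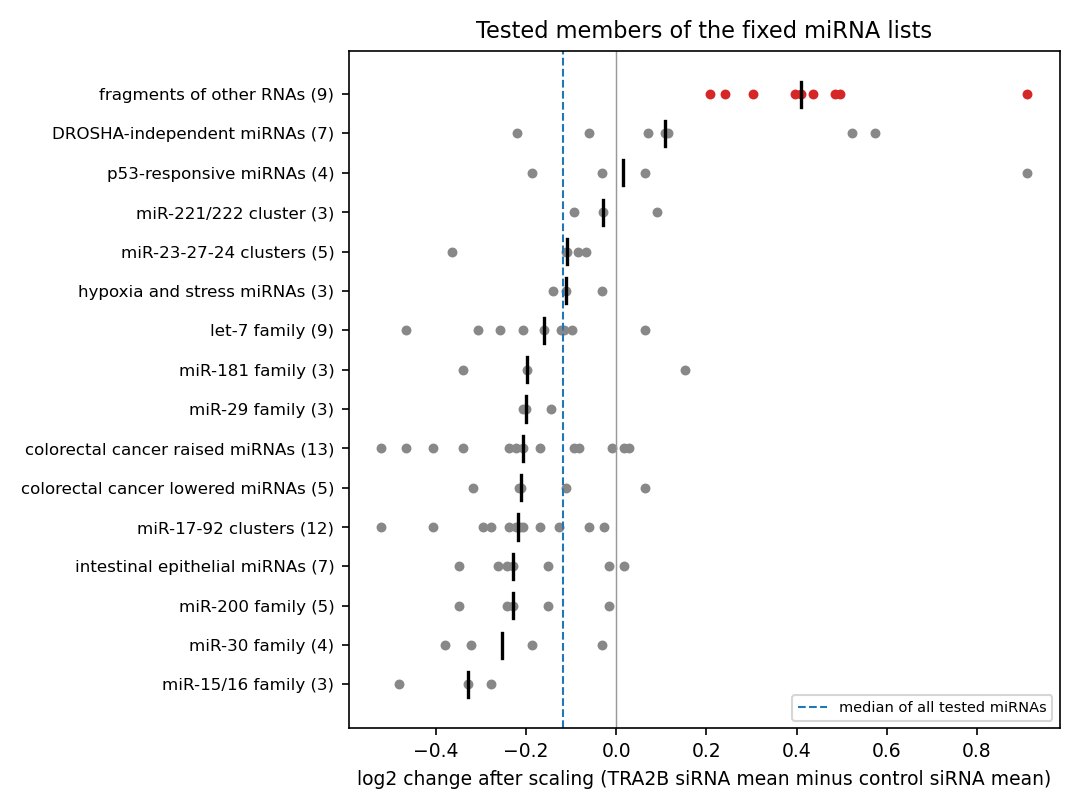
Each point is a tested member of a fixed list (number of members in brackets), placed by its scaled log2 change (mean of 2 TRA2B siRNA arrays minus mean of 2 control siRNA arrays) on the x axis, and black bars mark list medians. The fragments of other RNAs, in red, lie above 0 (median 0.41), while most families lie near the dashed median of all 135 tested miRNAs (-0.12).

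Families cut by DROSHA and DICER from hairpin precursors lay near or below the median of all tested miRNAs, and none of these lists passed after scaling. The 9 tested let-7 members, which restrain growth genes such as RAS and MYC, had a median change of -0.16 (camera adjusted p = 0.53), with 6 lower on both slides, where 72 of all 135 tested miRNAs were. The 12 members of the miR-17 to miR-92a cluster and its paralogs had a median of -0.22 (adjusted p = 0.19), with 10 lower on both slides. The 3 of the family of miR-15 and miR-16, which act on cell-cycle genes, had -0.33 (adjusted p = 0.19), with 3 lower on both slides. The 5 members of the miR-200 family, which maintain the epithelial state, had -0.23 (adjusted p = 0.45), with 4 lower on both slides. With the slide block, 1 let-7 member fell (miR-98), 2 of the miR-17 to miR-92a clusters fell (miR-18a and miR-92a), 1 of the family of miR-15 and miR-16 fell (miR-15b) and 0 of the miR-200 family. The falls of miR-98 (-0.11 and -0.83 on slides 1 and 2) and miR-18a (-0.16 and -0.88) came mostly from slide 2, and that of miR-92a (-0.76 and -0.05) from slide 1, whose control array carried blood-cell miRNAs. Adjusted over the list alone, the blocked counts were 1, 2, 2 and 0, and the unblocked counts were 0 in each. Before scaling, the blocked fit called all 9, 12, 3 and 5 members lower, as it did 112 of all 135 tested miRNAs. Scaling by the 75th percentile over all human probes, a factor at background level on these arrays, moved the median of all tested miRNAs to 0.67 and those of these 4 families to between 0.51 and 0.68. That shift tells nothing of their direction relative to the rest.

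Among the remaining families, the median changes were -0.20 for the 3 members of miR-29, -0.25 for 4 of miR-30, -0.11 for 5 of the clusters of miR-23, miR-27 and miR-24, -0.03 for 3 of the cluster of miR-221 and miR-222 and -0.20 for 3 of miR-181. The 13 tested miRNAs known to be raised in colorectal cancer had -0.21, with miR-18a, miR-203 (-0.05 on slide 1 and -0.89 on slide 2) and miR-92a lower in the blocked fit, each mostly on 1 slide. The 5 known to be lowered had -0.21. The 7 tested intestinal epithelial miRNAs, 5 of them the miR-200 family, had -0.23, and miR-192, miR-194 and miR-215 of that list were not tested. The 3 hypoxia and stress miRNAs had -0.11. The 4 p53-responsive miRNAs, which include miR-1246 of the fragments list, had 0.02, where miR-34a stood at 0.06 ± 0.48 (SE). The 7 DROSHA-independent miRNAs, which include products of spliced introns, had 0.11 (camera adjusted p = 0.24), with 2 higher in the blocked fit, miR-1234 (0.57 ± 0.15, SE) and miR-1225-5p (0.52 ± 0.15), and miR-320a at 0.11 ± 0.27 without the block. No other list of these passed (camera adjusted p from 0.19 to 0.87 over the 15 lists that did not).

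Markers of other cell types were mostly not detected. No muscle marker and no pluripotency or placental cluster miRNA was detected on any array. Tested were 2 mesenchymal and endothelial markers (median change -0.12) and 2 liver and neural markers (-0.22). So were 2 members each of the family of miR-103 and miR-107 (-0.18) and the miR-183 cluster (-0.09), too few for a list test. The blood-cell miRNAs were an exception on 1 array. MiR-451, a red-cell miRNA matured without DICER and the sole member on the array of its own list, had a total gene signal of 1067 with control siRNA 1 and of 1.55, -1.49 and -3.69 with TRA2B siRNA 1, control siRNA 2 and TRA2B siRNA 2. MiR-486-5p, another red-cell miRNA, had 404 with control siRNA 1 and values below 0 on the other arrays, and miR-223 of myeloid cells and platelets had 32.1, 7.07, 1.94 and 0.69 in the same order. Of the 9 haematopoietic markers, 5 were detected with control siRNA 1, 1 with TRA2B siRNA 1 (miR-142-3p) and 0 on either array of slide 2, and none could be tested. This array is the control of slide 1. Of 9 tested miRNAs that are also abundant in red cells, a set chosen after the data were seen, 4 had a lower scaled change on slide 1 than on slide 2, such as miR-92a (-0.76 against -0.05), and 5 a higher one, such as miR-425 (-0.35 against -1.08).

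**Figure D3:**
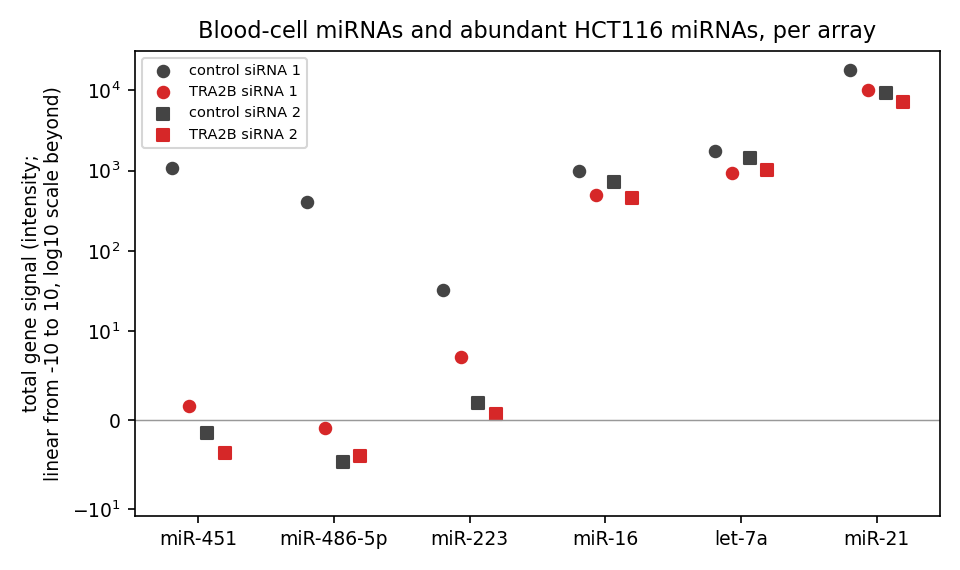
The total gene signal of 3 blood-cell miRNAs and 3 abundant HCT116 miRNAs is shown for each array, grey for control siRNA and red for TRA2B siRNA, circles for slide 1 and squares for slide 2, on an axis that is linear between -10 and 10 and logarithmic beyond. MiR-451 (1067) and miR-486-5p (404) stand out with control siRNA 1, while miR-16, let-7a and miR-21 are bright on all 4 arrays.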

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

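All explanations in this part were tested after the results they concern had been seen. Groups of 2 arrays are too small to look for outlying arrays.

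Human miRNAs outside the comparison and brighter than the median tested miRNA of their array were miR-451 and miR-486-5p, with total gene signals of 1067 and 404 on control siRNA 1, where the median tested miRNA had 124. All 32 spots of their 4 probes (100%) exceeded the negative controls by 3 SD on that array and 0 did on the others, which argues against a scratch or dirt. RNA of blood cells in that sample remains a candidate source, since 5 of 9 haematopoietic markers, a list written before the data were examined, were detected there, and miRNAs that red cells share with HCT116 (9 tested of a list of 13) should then also be higher on that array. Before scaling, their slide 1 change lay below their slide 2 change by 0.12 more than that of the other miRNAs (gap of -0.12 on the log2 scale). Without this comparison with the others, 6 of the 9 unscaled differences lay below 0 (down to -0.85 for miR-92a). The other 3 lay above it (up to 0.18 for miR-425). After scaling, 4 lay below 0 and 5 above it, so the majority turned with the scaling. As low a gap was found in 13.9% of 10000 random lists of like level. The blood-cell source therefore stays open, and the slide 2 values do not depend on it.

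The lower signal of most miRNAs before scaling on both slides could come from less labelled RNA on the TRA2B siRNA arrays, from unequal loss of dim and bright signal, from RNA breakdown, or from a lower miRNA content of the cells. Less labelled RNA as the whole cause would leave no gap between kinds of RNA, if it lowers every kind alike, which was not tested. Fragments of other RNAs exceeded the other tested miRNAs by 0.48 on slide 1 and by 0.51 on slide 2. This gap is the one already reported above, so its outcome was known and it adds no separate evidence. It argues against a common factor as the whole cause, and leaves open that less labelled RNA is part of the cause. For the median of the list, the same gap also argues against a dependence on signal level. Of 10000 random lists drawn from the 20 tested miRNAs nearest in level to each fragment, 0.01%, the smallest share they can give, changed as high. Few tested miRNAs were as bright as miR-720 and miR-1274b (5.62 and 4.02 on the scaled log2 scale with control siRNA). Their stand-ins were mostly dimmer, so such a dependence stays open for these fragments. More broken-down RNA with TRA2B siRNA cannot be told apart from a lower miRNA content: 1 of the 9 fragments, miR-1246, was higher before scaling on both slides, or 0 of 9 by the total gene signal. But the labelling controls were at background, so the yield per array is unknown. The 5 bright control probes had a median change of -0.43 on slide 1 and of -0.001 on slide 2. A lower content of DROSHA- and DICER-made miRNAs with TRA2B siRNA stays open and untested beyond these values.

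In data outside the comparison, array entries for 2 viral miRNAs, of Epstein-Barr virus, were called detected on all 4 arrays, out of 88 viral miRNAs. Whether their signal comes from viral RNA was not tested, and a detection call does not show it. Ebv-miR-BART12 had its highest total gene signal, 66.6, with TRA2B siRNA 1 (65.5, 11.3 and 21.6 with control siRNA 1, control siRNA 2 and TRA2B siRNA 2), and ebv-miR-BART13 its highest, 17.2, with control siRNA 1. Both were dimmer on every array than the median tested miRNA, which had 124 and 76.9 with control and TRA2B siRNA 1, and 55.9 and 36.3 with control and TRA2B siRNA 2.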

How the results depend on the processing

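The number of miRNAs past the threshold was 0 without a block under every alternative run, including each array left out. With the replicate block, which is also the slide, it was 29 as scaled, and with added settings chosen after seeing the data it was 114 with no scaling, 3 with bright control probes, 26 with quantile normalization, 41 with normexp, 21 with the total gene signal, 22 with a floor at the 20th percentile and 28 for miRNAs detected on all 4 arrays. The block removes a slide difference larger than the group difference, and the cause of the differences between scalings was not tested. The overall signal was negative throughout, -0.63 with the replicate block, -0.39 from median signals and from -1.14 to -0.12 with an array left out.

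The count of lists past the threshold, 1 as reported and 1 with the replicate block, was 4 with no filter (miR-17 to miR-92a clusters, miR-200 family and intestinal miRNAs added as lower), 4 with normexp (let-7, miR-17 to miR-92a clusters and the miR-15 family added as lower), 0 with an estimated correlation, 0 with fry, and 1 to 2 with an array left out. The let-7 family was the added list without control siRNA 1 and without TRA2B siRNA 2, and the haematopoietic markers without control siRNA 2, where control siRNA 1, the array with the blood-cell miRNAs, is the whole control arm, so that this restates its signal. Leaving out 1 array sets slides against each other and assumes that the lone array varies like the others. The fragments of other RNAs exceeded the others under every alternative, by 0.46 to 0.68 with an array left out, by 0.27 with no filter and by 0.23 with normexp. Their shift of 0.54 lost its call with an estimated correlation (adjusted p = 0.59), a test that called 0% of simulated shifts of 0.5. The simulated noise was independent between miRNAs, so the simulations do not vouch for the call at the preset correlation.

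Of the 72 named miRNAs, 12 kept the reported sign under every alternative. Among the 1220 values of these 72 under the alternatives, 152 turned sign. Of those, 43 turned with the percentile over all probes, which moved the median of all tested miRNAs from -0.12 to 0.67. The threshold was passed by 79 of the 1220. None had passed it as reported. Some settings chosen in advance gave no value. A floor at the 1st percentile lies below 0, the median over all human probes lies at the floor (72.95% to 86% of probes), and the mean signal is not in these files. With no filter most miRNAs sit at the floor with no spread, so that fit is unreliable. Low signal over background on slide 2 limits all values there.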

Other observations

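Both hypotheses were tested after the changes of the miRNAs concerned had been seen.

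Of the 135 tested miRNAs, 128 have a miRNA gene in the RefSeq gene table for GRCh38.p14 and 7 do not. These 7 array entries, chosen by that table, are miR-1274a, miR-1274b, miR-1280, miR-1308, miR-720, miR-886-3p and miR-923. The spelling of miR-29b-1* was matched to its gene only after a first run had left it without one. The median scaled change of the 7 was 0.41, against -0.13 for the rest, a gap of 0.54 (permutation test, two-sided, 100000 resamples over miRNAs, which are not independent, p = 0.0037), and 7 of the 7 were higher on both slides. Of the 7, 6 belong to the fragments of other RNAs and miR-923 was already the miRNA with the clearest separation, so this restates those results and is not separate evidence. The 3 fragments that still have a gene had a median of 0.49.

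Passenger strands were set against their guide strands, because both come from one hairpin. In 6 of 6 pairs the star strand stood higher relative to its guide with TRA2B siRNA (mean gap 0.20 ± 0.16, SD over pairs, exact sign test, two-sided, p = 0.031), and in 5 pairs on both slides. The widest gap was that of miR-21* (0.45) over miR-21 (-0.01), and that of miR-7-1* (0.07) over miR-7 (-0.26) came next. Random miRNAs of the same level put in place of the star strands gave a mean gap as large in 10.3% of 10000 draws, so a difference between the strands was not shown beyond that expected from their signal level.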
